A study of Homo sapiens with 18 samples.

How the data were processed

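RNA of MCF7 cells, 200 ng per sample by the stated protocols, had been labelled with the 3′ IVT Express kit and hybridised to 18 Affymetrix arrays. The deposited values are log2 expression levels that the authors made with RMA, which corrects background, scales arrays and summarises probes into probe sets, per the submitters' processing notes; the version is not given in the sources used here. Whether the 18 arrays were normalized together is not given either. The array medians over all probe sets ranged from 4.00 to 4.21, and their distributions were close but not identical. Slide and scan date are not given in the sources used here. Counts and depth do not apply to arrays, so the number of arrays limits the precision.

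Samples were grouped by their titles into 6 groups of 3 arrays. The table held 49386 probe sets, of which 93 are controls. By the platform annotation given, 45259 probe sets have 1 gene symbol, 1327 have several and 2800 have none here; 45178 of the first had an identifier found in the gene table, and 0 symbols were updated. Each of 18239 genes was represented by its probe set with the highest mean over all arrays, among those with 1 symbol. Of genes called with a change of at least 1 on the log2 scale and having several probe sets, 1 of 511 in shContr and 2 of 676 in shSTAT3 cells had another probe set changed as much the other way. TP53 was not analysed here. No coordinates are given, since no genome came with the series.

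Each comparison was fitted on the log2 values with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, group means, no covariate), and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Parental cells at 8 h were fitted on the 6 parental arrays, the 4 h effects, the line differences and their interaction on the 12 shRNA arrays, and the difference between the parental and shContr responses on the 6 parental and 6 shContr arrays. The design, the gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. There were 26 gene lists with 749 members, 695 of them measured. Lists can share members. BBC3, BAX, FAS, TNFRSF10B, PMAIP1 and APAF1 are on both the p53 and the proapoptotic list. XPC, DDB2 and POLH are on the p53 and DNA repair lists. SESN2, on the ATF4 list, and ACTA2, on the mesenchymal list, are p53 list members too. BIRC5 is on the G2/M, antiapoptotic and STAT3 target lists. Results of such lists are not independent of each other. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Camera compares the members with all other genes, whereas fry asks whether they change at all. With an estimated correlation camera takes its degrees of freedom from the arrays, so few arrays weaken its p-values. In both shRNA lines the nutlin-3a calls lost with an estimated correlation stayed under 0.05 with fry. Fry also passed lists that camera did not call, so this does not back the lost calls. The parental calls under the labels as given were lost with fry too (adjusted p = 0.787 each). A list's count of members passing is taken over all genes tested; "adjusted over the list alone" marks the other count. Lists that passed in no nutlin or line comparison at 4 h were JAK-STAT components, antigen presentation, antiapoptotic genes, luminal epithelial markers, endothelial and immune markers, ribosomal proteins and autophagy.

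Named genes were, per comparison, the 8 largest rises and falls among passing genes whose groups of arrays did not overlap, the 6 smallest adjusted p each way for interactions, up to 3 members of passing lists with the smallest adjusted p, up to 3 members of the p53, G1/S, G2/M, STAT3 target and apoptosis lists in every case, and STAT3, MDM2 and CDKN1A always; the text gives a selection of these.

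The numbers 1 to 3 in the titles recur in every group. Deviations from the group means correlated between same-numbered arrays in shContr cells (0.327, 0.224 and 0.309), each best with its own number. No correlation in the other pairs of groups exceeded 0.1, and those of the parental arrays were -0.69, -0.899 and -0.55. The numbers therefore pair arrays within shContr cells, as read from the data. With a block for this pairing 5412 genes passed for nutlin-3a in shContr cells and 4999 in the interaction of the lines, against 4840 and 4356 without it.

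The procedure was tested on simulated data with 18239 genes. For nutlin-3a in shContr cells it recovered 58% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1. For the interaction it recovered 90% of those changed by 1, and for the parental comparison 82%. The simulated parental spread left out both arrays labelled 2, a choice made after seeing the data. The 82% therefore does not describe the parental fit that keeps all arrays under their labels. Alternatives were a fit of all 18 arrays, an intensity trend with robust prior, array weights, a mean log2 minimum of 6, an offset of 64 on the linear scale, quantile normalization, median centring, the mean of probe sets, leaving out probe sets with an ID ending in _s_at, _x_at or _a_at (which match several genes, hold unspecific probes, or match several transcripts of 1 gene; called probe sets with a suffix), a log2 change of at least 1, the replicate block, and leaving out 1 array at a time. Added after seeing the data were fits without both parental arrays labelled 2, fits without both shContr arrays numbered 1, fits with the actin 3′ to 5′ difference or the mean poly-A control level as a covariate, and the block within shContr cells. For the untreated and the treated line differences, only the shContr array numbered 1 in the groups compared was left out. No array pair held identical values. Parental arrays stayed under their labels throughout.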

Results

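Gene expression was measured in MCF7 cells, an established human breast carcinoma line, on 18 Affymetrix arrays in 6 groups of 3 arrays. Nutlin-3a is a small molecule that blocks the binding of MDM2 to p53 and so stabilises p53. Parental cells were left untreated or received 10 µM nutlin-3a for 8 h. Cells stably carrying a lentiviral control short hairpin RNA (shContr) or one against STAT3 (shSTAT3), a transcription factor activated by cytokine receptors, were left untreated or received 10 µM nutlin-3a for 4 h. Values are deposited log2 RMA expression levels of 18239 genes, each read from 1 probe set. The number of arrays limits the precision. Nothing in the labels says that arrays of a group came from separate cultures, so adjusted p-values measure only the spread between arrays, with 1 line per hairpin.

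The targeted gene was examined first, as a check of the labels. STAT3 stood at 7.87 ± 0.04 (SD, n = 3) on the log2 scale in untreated shContr cells and at 6.16 ± 0.12 (SD, n = 3) in untreated shSTAT3 cells, a difference of -1.71 (SE 0.08, adjusted p = 2.54e-07). After nutlin-3a it stood at 9.07 ± 0.04 (SD, n = 3) and 7.94 ± 0.09 (SD, n = 3), a difference of -1.13 (adjusted p = 4.15e-07). STAT3 itself rose with nutlin-3a, by 1.20 in shContr cells (adjusted p = 1.39e-07) and by 1.78 in shSTAT3 cells (adjusted p = 2.04e-09), so that treated shSTAT3 cells had about the level of untreated shContr cells. The rise was larger in shSTAT3 cells by 0.58 (SE 0.12, adjusted p = 0.00281) with the probe set used, whereas the other 2 STAT3 probe sets gave 0.68 and 0.05.

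The parental arrays address which genes respond to 8 h of nutlin-3a. CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, was at 9.41 and 9.48 on the arrays labelled untreated 1 and 3 but at 13.21 on the array labelled untreated 2. It was at 13.18 and 13.14 on the arrays labelled nutlin 1 and 3 but at 9.29 on the array labelled nutlin 2. MDM2, a p53 target and the protein that nutlin-3a binds, showed 11.20 on the array labelled untreated 2 and 7.48 on the array labelled nutlin 2, against 7.42 and 7.44 on the other untreated arrays and 11.32 on each of the other nutlin arrays. The death receptor FAS and STAT3 followed the same order. All arrays were kept under their labels. With these labels no gene passed in limma (270 genes had an unadjusted p under 0.05), and the labelled group means of CDKN1A were 11.87 ± 2.23 (SD, n = 3) with nutlin-3a and 10.70 ± 2.17 (SD, n = 3) without. Camera called the p53 targets, CDKN1A and MDM2 among them, with a median of 0.76, and the G1/S and G2/M lists with -0.37 and -0.58, but the adjusted p was 0.714 for each with an estimated correlation.

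**Figure D1:**
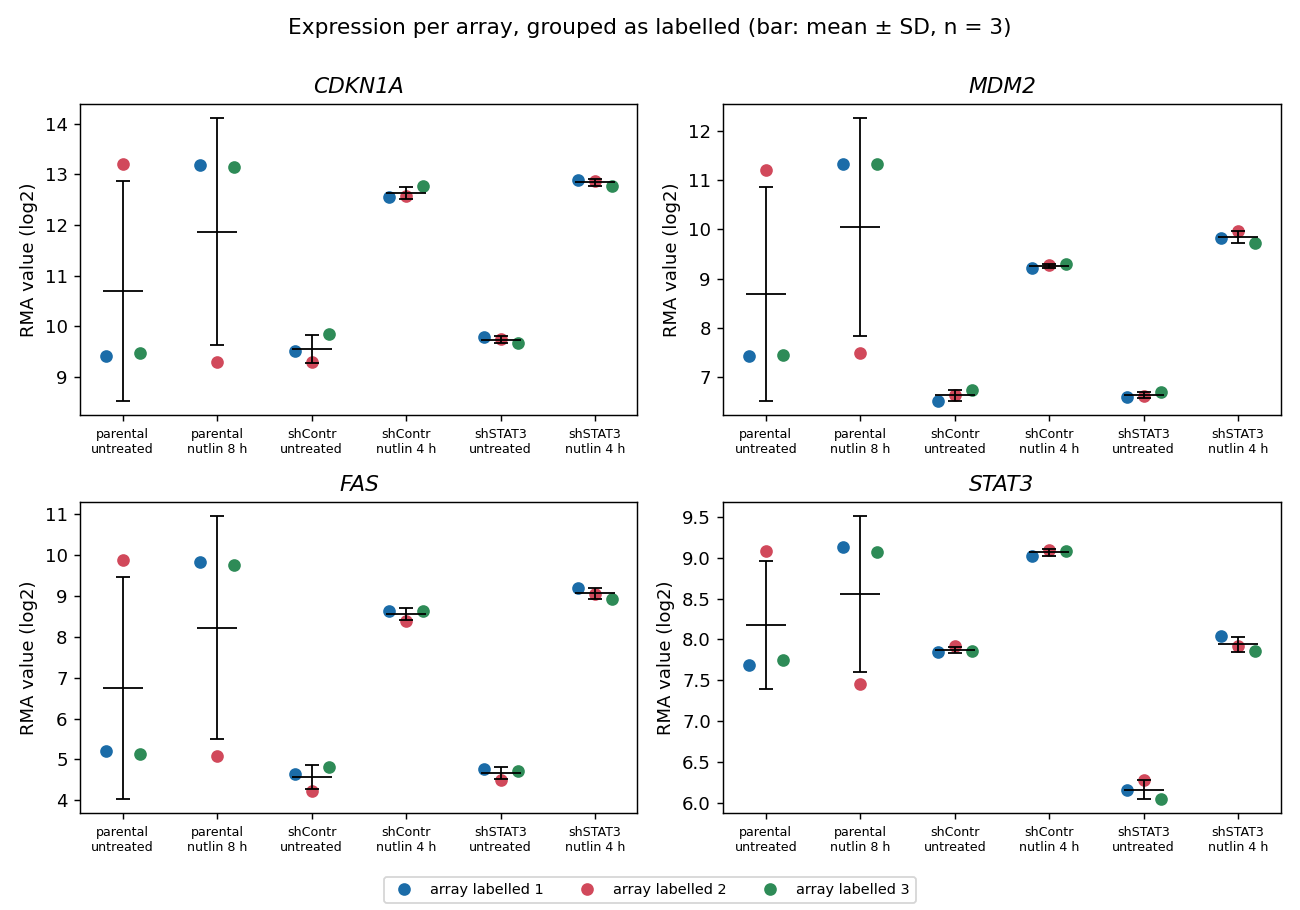
Deposited log2 RMA values (vertical axes) of CDKN1A, MDM2, FAS and STAT3 on each of the 18 arrays, grouped on the horizontal axes as labelled; points are arrays, coloured by replicate number, and bars give the group mean ± SD (n = 3). The parental array labelled untreated 2 has a CDKN1A value of 13.21 and the one labelled nutlin 2 a value of 9.29, whereas the shRNA groups separate by treatment.

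With both parental arrays labelled 2 left out, a choice made after seeing the data, 2936 genes passed, 1241 higher and 1695 lower with nutlin-3a. Because the arrays were left out for their values, the contrast is favoured by that choice and its p-values describe only the 4 arrays left, not an independent test. The p53 target list, fixed before the data were examined, had 40 of 44 measured members higher (41 adjusted over the list alone), with a median of 2.24. Camera gave an adjusted p of 1.21e-44 for it, and an adjusted p = 0.0887 with an estimated correlation. The largest rises were those of SERPINB5, which encodes maspin, at 6.79 (SE 0.12, adjusted p = 1.24e-06), NHLH2 at 4.95, TP53I3 at 4.91, FAS at 4.63, ACTA2 at 4.53, SERPINF1 at 4.43, the cytokine LIF at 4.37 and GDF15 at 4.33. All 39 members of the G2/M list were lower, among them PLK1 (-2.50), KIF23 (-2.72) and CENPA (-2.61). Of 38 G1/S and replication genes 34 were lower and 1 higher, the lower ones including the replication factor gene MCM10 (-2.82) and UHRF1 (-3.06). The largest falls were those of CDCA7 (-3.73), ZNF367 (-3.58), FAM111B (-3.27) and CCNE2, a G1/S cyclin (-3.16). With an estimated correlation the adjusted p was 0.299 for the G2/M list and 0.122 for the G1/S list. Immediate early genes were higher in 16 and lower in 2 of 28 cases (adjusted p = 0.379 with an estimated correlation), proapoptotic genes higher in 8 and lower in 2 of 24 (0.299), ATF4 genes higher in 8 and lower in 1 of 27 (0.302), and DNA repair genes lower in 13 and higher in 4 of 22 (0.302). Basal epithelial genes were higher in 7 of 18 (0.299) and NF-kappaB genes in 6 of 27 (0.421), with none lower.

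In shContr cells 4 h of nutlin-3a raised p53 targets and lowered genes of mitosis. MDM2 rose by 2.62 (SE 0.09, adjusted p = 9.8e-11), from 6.63 ± 0.11 to 9.25 ± 0.04 (SD, n = 3 each), CDKN1A by 3.08, GADD45A by 3.47 and FAS by 3.99. In all, 36 of 44 p53 targets rose (37 adjusted over the list alone) with a median of 1.20, and none fell. Besides FAS, the largest rises were those of the matrix metalloproteinase genes MMP1 (6.12, SE 0.19, adjusted p = 4.6e-11) and MMP10 (from 2.53 to 7.54), FLRT3 (5.36), PHLDA1 (4.40), CAPN8 (4.37), TNFRSF11B, which encodes osteoprotegerin (4.15), and ALDH1A3 (3.98). All 39 G2/M genes fell, with a median of -1.35, for example NDC80 (-2.10), TTK (-1.97) and CDC20 (-1.46), and 27 of 38 G1/S genes fell (31 adjusted over the list alone), for example CDT1, a replication licensing factor (-1.79). The adjusted p with an estimated correlation was 0.00334 for the p53 and G2/M lists and 0.00612 for the G1/S list. The largest falls were those of TMPRSS2 (-2.34) and of the G2/M members CDC25C (-2.34) and ESPL1, the gene of separase (-2.22). Untreated MMP1 and MMP10 levels, 2.80 and 2.53, lay near the lowest values of these arrays (1.93 to 2.01), and detection calls were not used here, so log2 changes from such levels are differences of deposited values and not exact changes in RNA.

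Further lists moved in shContr cells. Of 28 immediate early genes 21 rose (23 adjusted over the list alone) and 1 fell, with ATF3 at 3.92, KLF4 at 2.62 and DUSP5 at 2.41, and 16 of 21 cholesterol synthesis genes rose (17 adjusted over the list alone), with HMGCS1 at 1.53. Their adjusted p with an estimated correlation was 0.00334 and 0.0251. Among proapoptotic genes 8 of 24 rose and 1 fell. The examples TNFRSF10B (1.96) and PMAIP1 (1.96) are also on the p53 list, so this result is not separate from that of the p53 targets. Of DNA repair genes 15 of 22 fell and 3 rose, BRCA1 falling by 1.44 on the log2 scale, and of estrogen receptor targets 12 of 26 fell and 3 rose, NRIP1 falling by 1.47. With an estimated correlation their adjusted p was 0.0251 and 0.0274, and it was 0.0251 for the proapoptotic list. ATF4 and stress-response genes rose in 10 of 27 cases and fell in 2 (adjusted p = 0.0251 with an estimated correlation). SESN2, also a p53 list member, rose by 1.89. Hypoxia and glycolysis genes rose in 14 of 28 cases and fell in 1, with ALDOC at 1.30, but the adjusted p was 0.294 with an estimated correlation. The STAT3 target list had 10 of 39 members higher and 5 lower, with MMP1 at 6.12 and TIMP1 at 1.16; camera gave an adjusted p of 0.0176, and the adjusted p was 0.168 with an estimated correlation. Interferon genes rose in 12 of 42 cases and fell in 3 (ISG20, 2.05), and NF-kappaB genes rose in 11 of 27 and fell in 3 (CXCL8, 1.90), with adjusted p = 0.0614 and adjusted p = 0.116 with an estimated correlation. Oxidative phosphorylation genes fell in 7 of 31 cases (COX6C by 0.36), with adjusted p = 0.294 with an estimated correlation. Among markers of other cell types, basal epithelial genes rose in 10 of 18 cases and fell in 2 (CD44, 2.38; adjusted p = 0.0523 with an estimated correlation) and mesenchymal genes in 5 of 27 (FN1 by 1.24; adjusted p = 0.0717 with an estimated correlation). The lists of endothelial and immune markers (3 of 21 higher, adjusted p = 0.318), luminal markers (4 higher and 7 lower of 24, adjusted p = 0.508), antiapoptotic genes (3 higher and 3 lower of 11, adjusted p = 0.641), JAK-STAT components (adjusted p = 0.641), antigen presentation (adjusted p = 0.359), autophagy (adjusted p = 0.756) and ribosomal proteins (0 of 36, adjusted p = 0.057) did not pass.

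Across the shContr arrays 4840 of 18239 genes passed in limma, 1944 higher and 2896 lower. Of these, 370 rose and 315 fell by at least 1 on the log2 scale. Without probe sets with a suffix (_s_at, _x_at or _a_at) 1340 of 8371 genes passed.

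In shSTAT3 cells 4 h of nutlin-3a changed 6251 genes, 3446 higher and 2805 lower. With the mean of the probe sets of a gene the balance turned over, to 2880 higher and 3061 lower. Over the same arrays the GAPDH 3′ minus 5′ difference went from 0.05 to 0.33 and the mean poly-A control level from 6.45 to 7.12. MDM2 rose by 3.20 (SE 0.09, adjusted p = 8.81e-12), from 6.64 ± 0.06 to 9.84 ± 0.12 (SD, n = 3 each), CDKN1A by 3.10, ZMAT3 by 3.31 and FAS by 4.40. Of the 44 p53 targets 39 rose (40 adjusted over the list alone) with a median of 1.80. The largest rises included CAPN8 (4.75), TNFRSF11B (4.49), NHLH2 (4.48), GFRA2 (4.37), EGR4 (4.36), GEM (4.35) and ATF3 (4.10). All 39 G2/M genes fell, with a median of -1.93, and 35 of 38 G1/S genes fell and 2 rose, with a median of -0.99. Among them were CENPA, the centromeric histone (-2.84), CDC20 (-2.50), the primase subunit PRIM1 (-2.59) and MCM2 (-1.97). The largest falls were those of PIMREG (-3.38), KIF14 (-3.08) and PRR11 (-2.87), then CENPA, DLGAP5 (-2.74) and DEPDC1 (-2.72). The adjusted p with an estimated correlation was 0.00179 for the p53 and G2/M lists and 0.00149 for the G1/S list.

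Immediate early genes rose in 27 of 28 cases in shSTAT3 cells and fell in 1, with FOSB at 3.44 and DUSP5 at 2.57, and cholesterol synthesis genes rose in 20 of 21, with MVD at 1.85 and LSS at 1.69. Their adjusted p with an estimated correlation was 0.00149 and 0.0195. The remaining calls were lost with an estimated correlation but kept with fry, with an adjusted p of at most 0.000763 (oxidative phosphorylation genes). Fry also passed lists that camera did not call, such as ATF4 genes (adjusted p = 2.79e-06 with fry, 0.697 with camera). Passing fry therefore does not back the lost calls. Proapoptotic genes rose in 11 of 24 cases and fell in 2, with the p53 effector BBC3 at 2.36 (adjusted p = 0.0914 with an estimated correlation), and DNA repair genes fell in 12 of 22 and rose in 3, with BARD1 at -1.42 (adjusted p = 0.0772 with an estimated correlation). Interferon genes rose in 18 of 42 cases and fell in 3, with IRF1 at 1.49, and heat shock genes rose in 10 of 21 and fell in 2, with HSPA4L at 1.70 (adjusted p = 0.101 with an estimated correlation for both). Negative regulators of STAT3 rose in 9 of 19 cases, SOCS1 by 1.42 and PTPRK by 1.27 (adjusted p = 0.101 with an estimated correlation). NF-kappaB genes rose in 13 of 27 cases and fell in 2 (LIF, 3.47), basal epithelial genes rose in 9 of 18 and fell in 2 (CAV1, 1.81), and mesenchymal genes rose in 8 of 27 and fell in 1 (ACTA2, 4.03), with adjusted p = 0.111, 0.174 and 0.0873 with an estimated correlation. Estrogen receptor targets fell in 7 of 26 cases and rose in 3 (PGR, -1.20), and oxidative phosphorylation genes fell in 12 of 31 (SDHC, -0.95), with adjusted p = 0.151 and 0.214 with an estimated correlation. The STAT3 target list had 13 of 39 members higher and 3 lower and did not pass (adjusted p = 0.0682). Without probe sets with a suffix 1802 genes passed and ANXA1, at 2.73 otherwise, was at -0.06.

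Both responses shared 1086 genes that rose, against 367 for independent lists, and 1267 that fell, against 445, while 579 moved in opposite directions, against 846. Both sets of calls used the same estimate of spread per gene, so they are not independent. The numbers for independent lists are therefore only a rough guide. Across all genes, which are not independent replicates, the log2 changes of the 2 lines had a Pearson correlation of 0.565 and a Spearman correlation of 0.313. At a change of at least 1 on the log2 scale the lines shared 223 rises and 145 falls, and 0 genes moved in opposite directions.

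**Figure D2:**
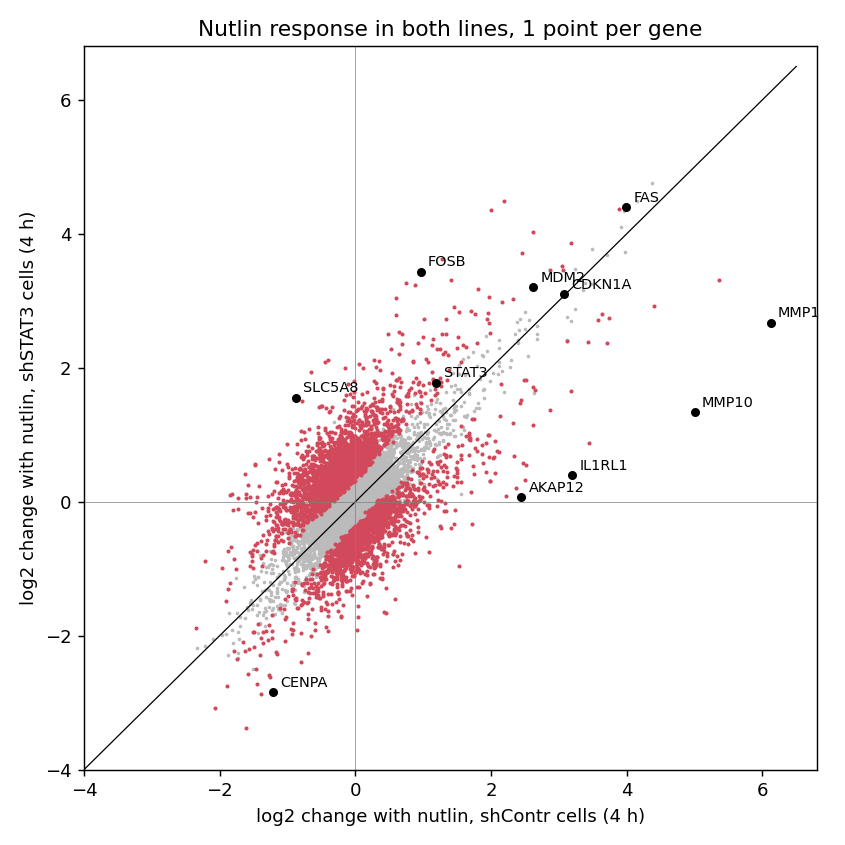
Log2 change with 4 h of nutlin-3a in shContr cells (horizontal axis) against shSTAT3 cells (vertical axis), 1 point per gene; red points are the 4356 genes whose response differed between the lines, the diagonal marks equal change, and named genes are in black. CDKN1A lies near the diagonal at 3.08 and 3.10, whereas MMP1 at 6.12 and 2.67 lies below it and FOSB above it.

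Without nutlin-3a the 2 lines differed in 474 genes, 109 higher and 365 lower in shSTAT3 cells. STAT3 had the largest fall. Also lower were AKR1C2, an aldo-keto reductase (-1.26, SE 0.13, adjusted p = 0.000255), KCNJ8 (-1.14), the integrin subunit ITGB6 (-1.12), the chemokine receptor CXCR4 (-1.07), LMO7 (-1.06) and CD44 (-1.05). SLITRK6 (1.42), GPNMB (1.41), SLC4A10 (1.32), NECAB1 (1.14) and ITPRID2 (1.01) were higher. Among 39 STAT3 targets 2 were lower, IRF1 (-0.53) and the gelatinase gene MMP9 (-0.48), and the list did not pass (adjusted p = 0.328). CDKN1A (0.19, adjusted p = 0.488) and MDM2 (0.01, adjusted p = 0.982) did not pass. Camera called small shifts of 7 lists, with medians from -0.24 for cholesterol synthesis to 0.16 for histones, but with an estimated correlation 0 lists passed. For example, 5 of 39 G2/M genes were lower, CDC20 at -0.37. With an estimated correlation the adjusted p was 0.249 for the G2/M, ATF4, cholesterol synthesis and histone lists, 0.307 for immediate early genes, 0.331 for G1/S genes and 0.643 for hypoxia genes. With fry these lists stayed under 0.05 apart from hypoxia genes (adjusted p = 0.26).

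The untreated comparison depended on the settings. Leaving out 1 array at a time gave between 134 and 324 genes, with 231 when the untreated shContr array numbered 1 was left out. On the untreated shContr array numbered 1 the actin 3′ probe set exceeded the 5′ probe set by 4.31, against 1.44 and 1.28 on the other arrays of its group. The poly-A spike-in controls of both shContr arrays numbered 1 averaged 5.40 and 5.52, against at least 6.47 on each other shContr array.

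After nutlin-3a the lines differed in 6252 genes, 3563 higher and 2689 lower in shSTAT3 cells, but 2863 higher and 3020 lower with the mean of the probe sets of a gene. MMP1 was lower by a log2 difference of -3.77 (SE 0.19, adjusted p = 2.8e-08), MMP10 by -3.73, FHL2 by -2.90, the interleukin-33 receptor IL1RL1 by -2.76, STAMBPL1 by -2.73 and AKAP12 by -2.53. SLC5A8 (2.55), NR4A3 (2.53), SERPINB5 (2.52), EGR4 (2.48) and EFNB2, an ephrin gene (2.33), were higher. Of 39 G2/M genes 28 were lower, CENPA by -2.01, and of 38 G1/S genes 26 were lower and 2 higher, MCM2 at -1.29, with adjusted p = 0.0466 and 0.0272 with an estimated correlation. Immediate early genes were higher in 16 of 28 cases and lower in 2, FOSB at 1.84 (adjusted p = 0.0466 with an estimated correlation). The p53 targets were higher in 30 of 44 cases and lower in 2, ZMAT3 by 1.59 and ASCC3 by 1.39, with adjusted p = 0.0816 with an estimated correlation. CDKN1A was not among them (0.20, adjusted p = 0.224). Hypoxia and glycolysis genes were lower in 16 of 28 cases (PGK1 by -0.78; adjusted p = 0.596 with an estimated correlation) and ATF4 genes lower in 12 of 27 and higher in 2 (SLC7A11, a cystine transporter gene, by -2.26; adjusted p = 0.0796 with an estimated correlation). Of the STAT3 targets 8 were higher and 8 lower, among them OSMR (-1.02) and BIRC5 (-1.23), and the list did not pass (adjusted p = 0.584). BIRC5 is also on the G2/M list, so its lower level is not separate from that of the G2/M genes.

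The control probe sets moved with this group. The GAPDH 3′ minus 5′ difference was 0.33 ± 0.08 (SD, n = 3) on the nutlin-treated shSTAT3 arrays, against -0.04 ± 0.05 (SD, n = 3) on the nutlin-treated shContr arrays and 0.05 ± 0.04 (SD, n = 3) on the untreated shSTAT3 arrays. The poly-A controls averaged 7.12 ± 0.25 (SD, n = 3), against 6.22 ± 0.61 and 6.45 ± 0.07 (SD, n = 3 each). NDRG1, a hypoxia-responsive gene, spread by an SD of 1.30 over the 3 treated shSTAT3 arrays.

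**Figure D3:**
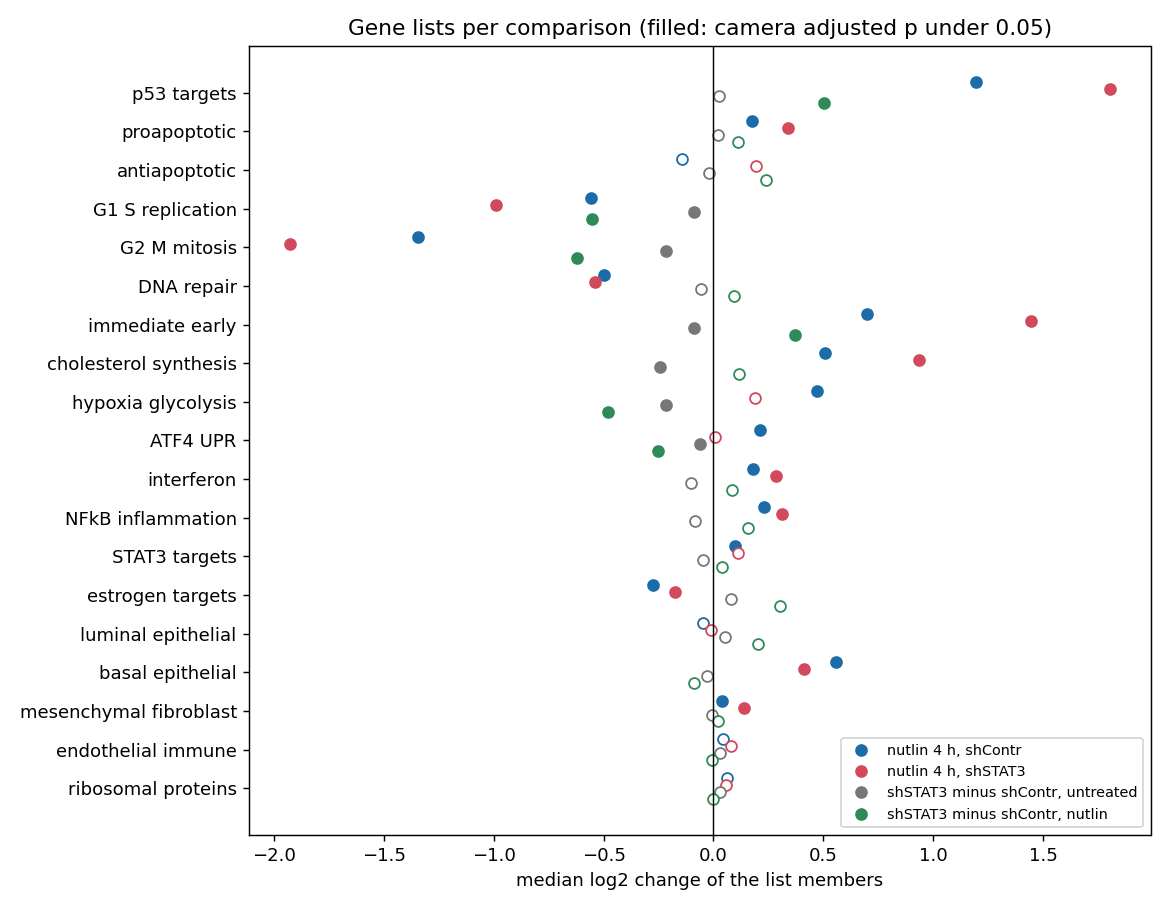
Median log2 change of the members of 19 gene lists (horizontal axis) in each of 4 comparisons, 1 colour each; filled circles passed camera with the preset correlation and open circles did not. The p53 list lies at 1.20 and 1.80 in the nutlin responses, and the G2/M list at -1.35 and -1.93.

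The difference between the 2 nutlin responses was tested as an interaction, and 4356 genes passed, 2739 with a more positive change in shSTAT3 cells and 1617 with a more negative one, against 2027 and 1892 with the mean of the probe sets of a gene. The smallest adjusted p-values belonged to MMP10 (-3.66, SE 0.14, adjusted p = 3.82e-09) and IL1RL1 (-2.81), which rose less in shSTAT3 cells from untreated levels near the lowest values of the arrays (MMP10 at 2.53 and 2.47), followed by AKAP12 (-2.38), STEAP4 (-2.18), SMAGP (-2.04) and DNAH7 (-1.55). In the other direction were FOSB (2.47, adjusted p = 2.91e-07), SLC5A8 (2.43), EHF, an epithelial ETS factor (1.96), the corepressor BCOR (1.91), PHLDB1 (1.84) and ZFHX3 (1.68). G1/S genes had a more negative change in 19 of 38 cases and a more positive one in 1 (PRIM1, -1.32), and immediate early genes a more positive change in 14 of 28 and a more negative one in 1, both with adjusted p = 0.0305 with an estimated correlation. The p53 targets had a more positive change in 24 of 44 cases and a more negative one in 2, with ZMAT3 at 1.90 and TP53I3 at 1.89, and G2/M genes a more negative change in 18 of 39, with CENPA at -1.63, with adjusted p = 0.149 and 0.13 with an estimated correlation. MDM2 differed by 0.58 (adjusted p = 0.00404) with the probe set used and by -0.12 to 1.37 over its 11 probe sets, and CDKN1A by 0.01 (adjusted p = 0.97). Cholesterol synthesis genes had a more positive change in 8 of 21 cases, LSS by 1.28 (adjusted p = 0.25 with an estimated correlation), but the median of that list, 0.39, was -0.20 without probe sets with a suffix. Heat shock genes had a more positive change in 7 of 21 cases and a more negative one in 1, HSPA4L at 1.38 (adjusted p = 0.241 with an estimated correlation), and negative regulators of STAT3 a more positive one in 8 of 19 and a more negative one in 1, CISH at 0.98 (0.149). Hypoxia genes had a more negative change in 4 of 28 cases, BNIP3L at -1.15 (0.735), and histone genes in 4 of 15 and a more positive one in 1, H2AC25 at -0.94 (0.241). The STAT3 target list had 7 members higher and 6 lower and did not pass (adjusted p = 0.728). With all 18 arrays in 1 fit 2656 genes passed.

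Parental cells at 8 h were compared with shContr cells at 4 h, which differ in time, infection and experiment together. With the labels as given 957 genes differed in their response, 491 with a more positive and 466 with a more negative change in parental cells (434 and 485 with the mean of the probe sets). The fit used 1 spread per gene for both experiments. CDKN1A had an SD of 2.17 and 2.23 in the parental groups, against 0.27 and 0.12 in the shContr groups. The adjusted p-values of this fit are therefore only a rough guide. MMP1 (-6.23, adjusted p = 7.59e-08), MMP10 (-4.91), CAPN8 (-4.49), GFRA2 (-3.82), IL1RL1 (-3.15) and ZNF365 (-2.94) had the more negative change. TMPRSS2 (2.26), STON1 (1.94), PDE7A (1.63) and CALHM2 (1.55) had the more positive change. The response of cholesterol synthesis and of hypoxia genes was more negative in parental cells, each with a median difference of -0.56. Camera with an estimated correlation gave adjusted p = 0.00279 and 0.00299. In parental cells under the labels as given the medians of the 2 lists were -0.016 and -0.040, against 0.51 and 0.47 in shContr cells. Labelled parental changes can be reduced by the arrays labelled 2, as for CDKN1A, which rose by 1.17 with them and 3.72 without. The small parental medians therefore do not show a lack of response. The values of -0.56 are differences between responses, not lower levels. The p53 list had a median of -0.49 and the G2/M list of 0.78, but without both parental arrays labelled 2 these medians were 1.15 and -0.43, and 3645 genes differed. With the replicate block 309 genes passed, 122 with a more positive and 187 with a more negative change. At a change of at least 1 on the log2 scale the balance was 170 and 259.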

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

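In this part, the tests of the parental arrays (positions, p53 target median and splits), of the GAPDH and poly-A interactions, of the dynamic range, of the STAT3 target list, and of the STAT3 probe sets and scaling were chosen after the result was seen. The actin and poly-A covariates were added after seeing the data, the actin test before its own result.

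A difference between groups was tested as an interaction for the 2 lines and 4356 genes passed. Of 100 permutations of the residuals, the real one included, 1 gave as many, and the highest other count was 1. Permuting single arrays treats them as independent and unpaired. It therefore speaks against chance between arrays only, not against a culture or batch effect on a group. With the block within shContr cells, added after seeing the data, 4999 genes passed. By gene the interaction was AKAP12 (-2.38), BCOR (1.91), DNAH7 (-1.55), EHF (1.96), FOSB (2.47), IL1RL1 (-2.81), MMP10 (-3.66), PHLDB1 (1.84), SLC5A8 (2.43), SMAGP (-2.04), STEAP4 (-2.18) and ZFHX3 (1.68). The list medians were 0.46 for p53 targets, -0.41 for G1/S, -0.42 for G2/M, 0.16 for negative regulators of STAT3, 0.47 for immediate early, 0.17 for heat shock, -0.23 for hypoxia, 0.39 for cholesterol synthesis and -0.25 for histones. With an estimated correlation the G1/S and immediate early lists kept their call (adjusted p = 0.0305 each), and the others lost it, with adjusted p = 0.149 for p53 targets and negative regulators of STAT3, 0.13 for G2/M, 0.241 for heat shock and histones, 0.735 for hypoxia and 0.25 for cholesterol synthesis, whose median was -0.20 without probe sets ending in _s_at, _x_at or _a_at.

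Between parental cells at 8 h and shContr cells at 4 h 957 genes differed in their response under the labels as given, tested as an interaction. Of 100 permutations, the real one included, 1 gave as many, and the highest other count was 920. Permuting residuals treats the arrays of both experiments as alike in spread. The SD of CDKN1A was 2.17 and 2.23 in the parental groups, against 0.27 and 0.12 in the shContr groups. These permutations therefore cannot judge chance between arrays. By gene the interaction was BRD8 (1.31), C14orf93 (1.58), CALHM2 (1.55), CAPN8 (-4.49), GFRA2 (-3.82), IL1RL1 (-3.15), MMP1 (-6.23), MMP10 (-4.91), PDE7A (1.63), STON1 (1.94), TMPRSS2 (2.26) and ZNF365 (-2.94). BRD8 was at -0.18 without probe sets ending in _s_at, _x_at or _a_at. The list medians were -0.49 for p53 targets, 0.78 for G2/M, -0.0468 for STAT3 targets, -0.21 for interferon, 0.30 for estrogen receptor targets, -0.45 for basal epithelial, -0.60 for immediate early, -0.56 for hypoxia, -0.56 for cholesterol synthesis and 0.19 for oxidative phosphorylation genes. With an estimated correlation the hypoxia and cholesterol synthesis lists kept their call (adjusted p = 0.00299 and 0.00279), and the others lost it, with adjusted p = 0.753 for p53 targets, 0.681 for G2/M, 0.258 for STAT3 targets, 0.0683 for interferon, 0.0671 for estrogen receptor targets, 0.487 for basal epithelial and oxidative phosphorylation genes and 0.449 for immediate early genes. Without both parental arrays labelled 2 the p53 and G2/M medians changed sign, to 1.15 and -0.43. Among 4040 probe sets without a single gene symbol, which no comparison used, 544 passed with nutlin-3a in shContr cells and 871 in shSTAT3 cells.

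The first pattern weighed is that the 2 parental arrays labelled 2 lie with the other group. On a scale from 0 for untreated 1 and 3 to 1 for nutlin 1 and 3 over the p53 targets, the array labelled untreated 2 lay at 1.004 and the one labelled nutlin 2 at -0.003. An array or RNA quality batch alone is argued against by a median of 2.171 for the array labelled untreated 2 over these targets, 43 of 44 higher. An exchange of the labels or of the treatments of these 2 arrays may explain it, as a hypothesis found on the same arrays, and no biological explanation was tested. The real count was 0 genes in limma (270 at an unadjusted p under 0.05), so all 10 splits of the 6 parental arrays had to reach it and their number tests nothing; the 5023 genes of the split grouping untreated 1 and 3 with the array labelled nutlin 2 show the same structure of the samples again and are no further evidence.

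The second pattern is that the lines differed in 6252 genes with nutlin-3a but in 474 without, with 4356 interactions. The actin 3′ to 5′ signal as the whole cause is argued against. With it as a covariate 99.6% of interaction genes with a change of at least 1 (726 of 729) kept call and direction. Of all 4356 interactions 3885 did so. The covariate stands out on 1 array, untreated shContr 1 at 4.31, so this fit rests largely on that array. A wider dynamic range stays open. Of 308 interactions in genes chosen by the mean response of both lines, 211 went with that response and 97 (31.5%) against it. With genes chosen by the shContr change 74.7% went against that change, and with genes chosen by the shSTAT3 change 5.13%. The share depends on the choice of genes, so it cannot decide the question. RNA or labelling quality stays open, since the GAPDH 3′ to 5′ difference had an interaction of 0.357 and 0 of 3 nutlin-treated shSTAT3 arrays lay within the range of the others, and so does a batch of its own, with a poly-A control interaction of 0.634; with the poly-A level as a covariate 4156 genes passed, 3785 of them shared with the 4356 in the same direction, so that level alone did not account for the count, but a batch need not follow it. Reduced STAT3 cannot be told apart from these: the STAT3 target list had an adjusted p of 0.728 with members going both ways, and there was 1 line per hairpin. For the 3 against 3 comparisons 10 splits are too few to judge chance: the real and highest other counts were 4840 and 0 for nutlin-3a in shContr cells, 6251 and 0 in shSTAT3 cells, 474 and 0 between untreated lines and 6252 and 0 between treated lines.

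The third pattern is the rise of STAT3 with nutlin-3a. Cross-hybridisation of 1 probe set is argued against by its 3 probe sets, which rose by at least 1.195 in both shContr and shSTAT3 cells. The smallest change with parental cells included, 1.172, comes from the fit without the arrays labelled 2 and is favoured by that choice, since with the labels as given the parental changes were 0.37, 0.38 and 0.51. Scaling between arrays is argued against by a rise of at least 1.184 in shContr cells after median centring or quantile normalization. A response of the STAT3 gene to nutlin-3a may explain it, but a direct effect of p53 was not tested.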

How the results depend on the processing

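Fits without the arrays labelled 2 of parental cells or numbered 1 of shContr cells and with control covariates were chosen after seeing the data. Over all alternatives 1517 of 1655 list results and 6087 of 6427 named-gene results kept direction and side of the threshold; 10 and 9 reversed. Without both parental arrays labelled 2, 2936 genes passed in parental cells and 3645 differed from shContr, with the p53 and G2/M medians of that difference at 1.15 and -0.43; with array weights they were 0.58 and -0.018 and 2729 genes differed, and without 1 array at a time the p53 median ran from -0.99 to 0.24 (0.21 without the array labelled nutlin 2, 0.24 without untreated 2) and the count from 619 to 1336. With an estimated correlation the passing lists fell from 3 to 0 in parental, 16 to 9 in shContr and 15 to 5 in shSTAT3 cells, 7 to 0 and 6 to 3 between untreated and treated lines, 9 to 2 in the line interaction and 10 to 2 for parental against shContr. Without probe sets ending in _s_at, _x_at or _a_at, the last for transcripts of 1 gene, 8371 genes were tested instead of 18239, and 1340, 1802, 112, 1766, 1132 and 285 genes passed in shContr, shSTAT3, untreated lines, treated lines, line interaction and parental against shContr; STAT3 targets (-0.00713 in shContr, 0.052 in parental against shContr), ANXA1 (-0.0630), immediate early genes (-0.000593 untreated), PGM5 (0.069), PPP1R1C (-0.028), ACTA2 (-0.25), cholesterol synthesis (-0.20), BIRC5 (0.11), FGB (0.023), PTPRK (-0.14) and BRD8 (-0.18) reversed, as did MCL1 (-0.052) in the interaction with the mean of probe sets. A change of at least 1 left 685, 929, 16, 681, 729 and 429 genes, and an overlap of 368 between the nutlin responses of both shRNA lines. With all 18 arrays in 1 fit 115 genes differed untreated, 2656 in the interaction and 1596 for parental against shContr. Untreated, the intensity trend gave 802, a mean of at least 6 gave 821, an offset of 64 gave 771, and leaving out 1 array 134 to 324 (171, 210 and 134 without shSTAT3 1, 2 and 3; 231 and 272 without shContr 1 and 3). Without both shContr arrays numbered 1, 387 genes differed for parental against shContr, where the replicate block gave 309. Fewer tested genes account for only part of the lower counts without probe sets of these endings, since the passing share fell too (1340 of 8371 against 4840 of 18239 in shContr cells), and beyond this the cause was not tested. Other counts stayed within 1.5 times, though the mean of probe sets turned the balance of directions over in shSTAT3 cells, between treated lines and for parental against shContr: leaving out 1 array gave 4223 to 4541 in shContr, 5430 to 5944 in shSTAT3 cells, 5401 to 5795 between treated lines and 3615 to 4249 in the interaction. Blocks of slide and scan date were not run, since the files do not give them. Signal over background limits genes of low level; no count of reads applies.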

Other observations

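All tests of the MAPK hypothesis in this part were chosen after the result was seen. MMP1, FLRT3, PHLDA1 and DUSP5 rose with nutlin-3a in shContr cells by 6.12, 5.36, 4.40 and 2.41, but in parental cells at 8 h, without the arrays labelled 2, by -0.12, 1.07, 0.92 and -0.09. A candidate explanation is higher output of the MAPK pathway, examined with a list of 9 other genes of that output. Its median was 0.77 in shContr cells (5 higher, camera p = 0.000124, p = 0.0107 with an estimated correlation) and 0.75 in shSTAT3 cells (6 higher, p = 0.000134, p = 0.0109 with an estimated correlation). In parental cells it was 0.31 (3 higher, p = 0.0245), which stays open, since p = 0.189 with an estimated correlation. In shContr cells DUSP4 rose by 3.13 and SPRY2 by 1.07, whereas CCND1 was at -0.23 (adjusted p = 0.128). ETV4 (0.05), ETV5 (0.16) and SPRY4 (0.15) did not pass in shContr cells either. No measure of MAPK activity itself is in the data, so the hypothesis stays untested at that level. Nor can the list tell MAPK output apart from an effect of p53 on its members, which was not tested.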
